A study of Mus musculus with 7 samples.

How the data were processed

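Total RNA of heart apex from 7 mice was labelled with Cy3 after conversion of 100 ng to cDNA, per the labels' protocols, and hybridised to 1-colour Agilent arrays of design 074809, all 7 on 1 slide read in 1 scan. The scanner images were quantified by the authors with Feature Extraction 12.0.3.1 and the protocol GE1_1200_Jun14, with probe positions on build mm9, per the file headers. The deposited array files hold, for each of 62976 spots, the processed signal as an intensity on a linear scale after background subtraction, the median signal and the median local background as intensities, and flags for saturation, outliers and signals well above background, per the file headers. The authors' deposited value table holds log2 values of 56745 probes. Set against the scanner signals, its columns matched log2 values that were quantile normalized between arrays and centred on each probe's median over arrays (r from 0.998 to 0.9998, slopes from 0.996 to 0.9996, across probes). Every column of it had a median of 0 and a mean of 0.0462, a direction is not in question because the columns are single arrays, and the software that made it is not given in the sources used here.

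From the scanner files, control spots and spots with an outlier flag were left out, log2 of the processed signal was taken, each array's 75th percentile over non-control spots was subtracted and the mean of these percentiles (9.14) was added back as a constant. Spots of a probe were averaged. Probes were named through their accession and a RefSeq gene table of GRCm38.p6: of 56605 non-control probes, 32994 matched a symbol and 23611 kept the file's own identifier. Of these probes 30538 were well above background on at least 3 of the 7 arrays, and any of them with a missing value was then left out. Each gene was represented by its kept probe with the highest mean, which left 23678 genes, 14720 with a symbol. The files carry no mean signal column, so the planned normexp alternatives used the median spot signal in its place. Coordinates of the RefSeq table are of another build than the arrays and were used only for which genes neighbour each other.

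DKO and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the single term, 5 residual and 2.11 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Probes of Akt1 and Akt2 were fitted in the same way among all kept probes. Gene lists fixed before the data were examined (38, of which 36 had at least 5 measured members and were tested) were tested with camera at a preset correlation of 0.01, adjusted separately over 24 pathway and technical lists and over 12 marker lists. These covered insulin and PI3K signalling, FoxO and ATF4 targets, protein turnover, stress responses, cardiac structure, ion handling, metabolism, translation, cell cycle, vessels, matrix, inflammation, the clock, immediate early genes and markers of 12 tissues or cell types. Sex-linked genes and the targeted genes formed the 2 lists too short to test. A list value per array is the median over members of the signal minus the member's control mean.

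Genes were named by a rule fixed before the data were examined, which covered Akt1 and Akt2; the 10 largest rises and 10 largest falls among called genes with a proper symbol and no overlap between groups; up to 4 members with the smallest p in each list described; and called members in counts. Genes not well above background on any array of a group were given a bound. Each mouse is a separate animal, per the labels, and no pair of arrays held identical values: arrays of 1 group correlated at 0.984 to 0.994 over kept genes. Arrays of different groups correlated at 0.978 to 0.990, so the ranges overlap. The overlap came from control replicate 1, which correlated at 0.984 to 0.987 with the other controls. Control replicate 2 correlated at 0.984 with control replicate 1 and at 0.989 to 0.990 with the DKO arrays. With control replicates 3 and 4 it correlated at 0.992 and 0.994.

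Alternatives covered quantile normalization, centring on the median of detected probes, normexp (offset 50) with either normalization, no filter and a filter on all 7 arrays, the authors' values, the mean of a gene's probes, trended and robust variances, array weights, the replicate number or slide row as a block, each array left out, and for lists an estimated correlation and fry. A pair of alternatives was added after seeing the data. The first left out up to 50 tested named genes on either side of Akt1 and of Akt2, fewer where the chromosome ended. The second was the exact permutation of list means. On simulated data with the means and spreads of the 23678 genes and 200 changed genes in the DKO against control comparison, the fit recovered 23.9% of changes of log2 0.5, 77.6% of log2 1 and 92.4% of log2 2, each with the right sign, with 7 false calls. A simulated shift of log2 0.5 in the FoxO list was called by camera, and 0 of 26 lists without a shift were called. In both simulations the genes varied independently. The real comparison called 1114 genes, more than the 200 changed here, so these rates need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.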

Results

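RNA from the heart apex of 7 male mice was measured on single-colour Agilent mouse expression arrays, with 1 array per mouse. In the 3 double knockout mice (DKO), Akt1 and Akt2 carried loxP-flanked exons, 6 and 7 in Akt1 and 5 and 6 in Akt2. In these mice MerCreMer, a recombinase that works only once tamoxifen reaches it, was expressed from the cardiomyocyte promoter of alpha myosin heavy chain. The 4 control mice carried MerCreMer alone. Both groups received 500 µg of hydroxytamoxifen per day for 5 days and were sampled 10 days after induction, at an age of 3 months. Akt1 and Akt2 encode serine/threonine kinases that relay insulin and growth factor signals. The comparison asks how heart transcripts differ once both genes are deleted in cardiomyocytes. Between 50.9% and 55.7% of probes were well above background on an array, with 0 saturated spots, and the number of arrays limits the precision. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were well above background on all 7 arrays, and the probe for Xist, the RNA of the inactive X chromosome, on 0 of them.

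Akt2 signal was lower in all 3 DKO hearts than in any control heart. Its brightest probe fell from 13.69 ± 0.07 (SD, n = 4) to 11.64 ± 0.03 (SD, n = 3) on the normalized log2 scale, which is 4.13-fold (limma, adjusted p = 0.000203 over probes). A dimmer Akt2 probe was 4.87-fold lower, at 10.20 ± 0.05 in control and 7.91 ± 0.17 in DKO, while the last probe fell by only 1.60-fold, from 9.93 ± 0.14 to 9.26 ± 0.20 (limma, adjusted p = 0.000295 and 0.0335). Akt1 showed no fall. Its brighter probe gave 14.48 ± 0.06 in control and 14.65 ± 0.04 in DKO, and its dimmer probe 8.27 ± 0.23 and 8.74 ± 0.24 (limma, adjusted p = 0.199 and 0.139). Where these probes lie relative to the floxed exons was not analysed here, and a probe outside the deleted part checks nothing. RNA of cells other than cardiomyocytes also enters every value.

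**Figure D1:**
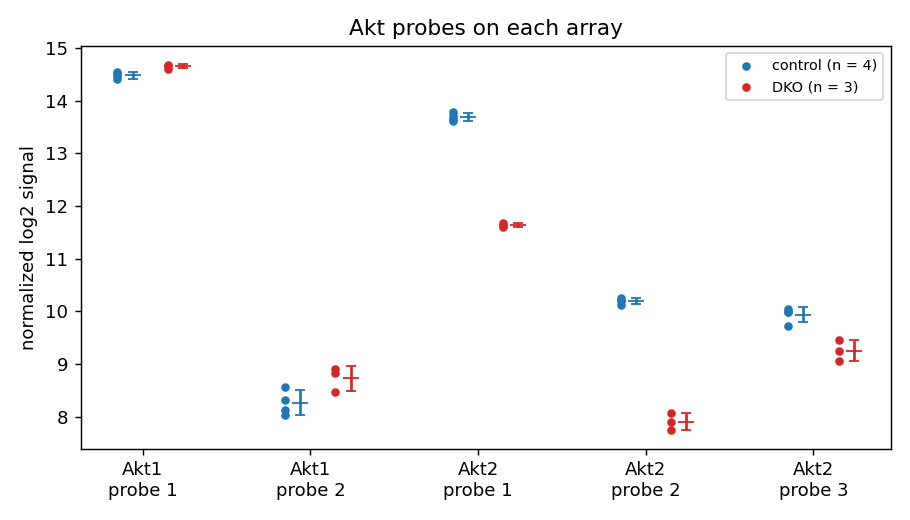
Normalized log2 signal of the kept probes of Akt1 and Akt2 on each array, with control arrays (n = 4) in blue and DKO arrays (n = 3) in red; the bar beside the points is the mean with its SD, and probes of a gene are numbered from bright to dim. The 3 Akt2 probes were lower in DKO, by 4.13-fold for the brightest, and the 2 Akt1 probes were not.

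Across 23678 genes, 1114 differed between DKO and control hearts at an adjusted p below 0.05 (limma, two-sided, Benjamini-Hochberg), 571 of them higher and 543 lower in DKO. Of these, 211 differed by at least 2-fold, with 77 higher and 134 lower. The filter asked for signal well above background on at least 3 of the 7 arrays. A gene seen only in controls could pass on 3 of the 4 arrays, but one seen only in DKO needed all 3. The excess of falls was therefore not separated from the filter. With probes above background on all 7 arrays, 140 genes differed by at least 2-fold, a count that was not split by direction. Large rises included those of Angptl4, Gdf15, Bex1 and Myh7, and large falls those of Lgals4, Tfrc and Akt2, among genes with a symbol. In 6080 genes (25.7%) the values of the groups did not overlap, where chance gives 5.71%. Leaving out 1 array kept the direction of every shared call, which such overlapping sets of arrays leave little room to change. The count moved to 712 without control replicate 1, 417 without control replicate 3, and 191 without control replicate 4. It was 160, 276 and 352 without DKO replicates 1, 2 and 3. With slide row, which the groups shared unevenly, as a block in the fit, 288 genes were called. The count at 2-fold became 374 without control replicate 2, 96 without control replicate 4 and 91 without DKO replicate 1.

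The 10 largest rises in DKO hearts included Angptl4, Ccn2, Myh7, Gdf15 and Derl3. Angptl4, a secreted inhibitor of lipoprotein lipase, rose 5.48-fold (log2 difference 2.45 ± 0.23, SE, n = 4 and 3, adjusted p = 0.00677 by limma), and Ccn2, a matricellular growth factor, 3.98-fold (log2 1.99 ± 0.13, adjusted p = 0.00312). Myh7, the beta myosin heavy chain that predominates in the fetal mouse ventricle, rose 4.30-fold (log2 2.11 ± 0.21, adjusted p = 0.00778). The stress-induced secreted factor Gdf15 rose 4.89-fold, Bex1 4.88-fold, the retinol carrier Rbp4 3.86-fold, the growth factor Fgf6 3.57-fold, the ribonuclease Rnase1 4.18-fold and the NMDA receptor subunit Grin2c 3.29-fold. Derl3, a component of ER-associated degradation, had the largest difference at log2 4.60 ± 0.93 (adjusted p = 0.0418 by limma), but its probe was well above background on 1 of the 4 control arrays, so the size of this rise is poorly defined. Rnase1 was above background on 3 of the 4 control arrays. With single arrays left out, Angptl4, Bex1, Myh7, Ccn2, Rbp4 and Fgf6 passed in all 7 fits, while Derl3 passed in 1, Gdf15 in 3, Rnase1 in 4 and Grin2c in 6. The adjusted p then reached 0.118 for Derl3 without DKO replicate 3, 0.0700 for Gdf15 and 0.0700 for Rnase1 without DKO replicate 2, and 0.05004 for Grin2c without DKO replicate 1.

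The 10 deepest falls included Tfrc, Dbh and Lgals4 beside Akt2 itself. Tfrc, the transferrin receptor, fell 4.77-fold (log2 -2.25 ± 0.32, SE, n = 4 and 3, adjusted p = 0.0167 by limma), and Dbh, dopamine beta-hydroxylase, 3.46-fold (log2 -1.79 ± 0.13, adjusted p = 0.00374). Lgals4, encoding galectin-4, fell 5.73-fold (log2 -2.52 ± 0.25, adjusted p = 0.00781); it lies 41 tested genes from Akt2 on chromosome 7 in the GRCm38.p6 gene order. Igsf1 fell 3.96-fold, Plekhh1 3.93-fold, the Nogo receptor Rtn4r 3.83-fold, the RNA-editing cofactor A1cf 3.49-fold and the noncoding RNA Uckl1os 4.05-fold. Ctcfl, a germline paralog of the insulator protein CTCF, was not well above background on any DKO array and was at least 2.02-fold lower there (adjusted p = 0.00650 by limma), so its place among the 10 rests on values at background. This bound sets the control mean against the DKO mean with each DKO value raised to the lowest signal that was well above background on its array. Of the DKO arrays, Rtn4r and A1cf were above background on 2, and Uckl1os on 1. Ctcfl, Lgals4, Akt2, Igsf1, Plekhh1 and Dbh passed in all 7 fits with an array left out, whereas Tfrc passed in 5, Rtn4r in 2, A1cf in 1 and Uckl1os in 1. The adjusted p then reached 0.0600 for Tfrc without control replicate 4, 0.0876 for Rtn4r without control replicate 4, 0.0946 for A1cf without control replicate 4 and 0.116 for Uckl1os without DKO replicate 2.

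**Figure D2:**
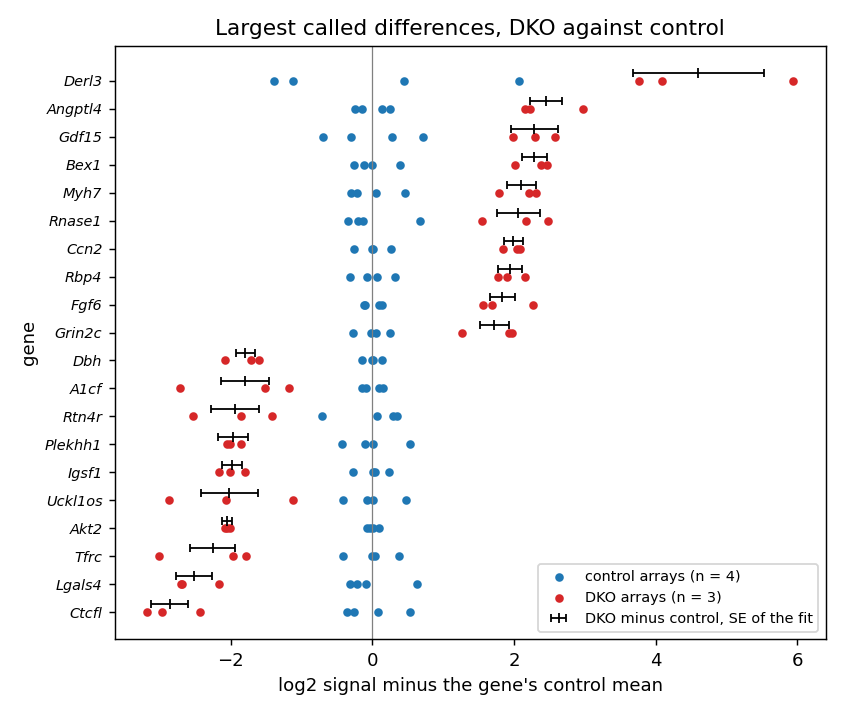
Log2 signal of the 20 genes with the largest called rises and falls, each array's value minus the gene's control mean, with control arrays (n = 4) in blue, DKO arrays (n = 3) in red and the fitted difference with its SE in black. Genes were drawn only from those without overlap between the groups, and the spread is widest for Derl3.

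Chaperones and folding enzymes of the endoplasmic reticulum were higher in DKO hearts. Of 24 measured members of the list for the ER and the unfolded protein response, 9 rose and 0 fell past adjusted p over all genes (19 and 1 adjusted over the list alone). In all, 22 of the 24 were higher, with a median log2 difference of 0.55. Besides Derl3, the members that rose were Dnajb9, an ER co-chaperone (0.76 ± 0.09), the secreted ER stress factor Manf (1.21 ± 0.16), the transcription factor Xbp1 (0.75 ± 0.10), Hyou1 (1.04 ± 0.14), Sdf2l1 (1.69 ± 0.24), Creld2, Hsp90b1 and Pdia4. The camera test with its preset correlation gave an adjusted p of 9.06e-10 for the list (adjusted p = 0.169 with an estimated correlation). Control replicate 1 stood apart in this list, at -0.18 against 0.06 to 0.07 in the other controls. The DKO arrays were at 0.53, 0.39 and 0.66. Without that control the median difference was 0.48. The related list of ATF4 targets, genes of the integrated stress response, had 5 of 30 members higher and 0 lower (7 and 3 adjusted over the list alone; median 0.09). These were the glutathione-degrading enzyme Chac1 (1.22 ± 0.08), the phosphatase subunit Ppp1r15a (1.05 ± 0.11), Cth (1.05 ± 0.13), Gdf15 and Atf5 (camera adjusted p = 0.0163; adjusted p = 0.169 with an estimated correlation). Chac1 and Ppp1r15a passed in all 7 fits with an array left out and 0 of the 9 ER genes did. The highest adjusted p was 0.118 for Derl3 without DKO replicate 3 and 0.133 for Atf5 without DKO replicate 1. The ATF4 median was 0.17 without control replicate 1 and 0.06 without control replicate 3. ATF4 targets lost their call under quantile normalization and with the authors' values, with adjusted p reaching 0.0866.

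Targets of FoxO transcription factors, which Akt phosphorylates and keeps out of the nucleus, rose as a group. Of 34 measured members 9 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 difference of 0.36 (camera adjusted p = 2.01e-09; adjusted p = 0.105 with an estimated correlation). They were the autophagy gene Gabarapl1 (0.97 ± 0.08), the mitophagy receptor Bnip3 (1.27 ± 0.13), the pyruvate dehydrogenase kinase Pdk4 (1.37 ± 0.14), the insulin receptor Insr (0.84 ± 0.10), Ccng2, the cell cycle inhibitor Cdkn1b, Txnip, Pik3ip1 and Pink1. In the insulin and PI3K pathway list, 4 of 35 members rose and 1 fell (7 and 4 adjusted over the list alone). The receptor adaptor Irs1 rose 2.12-fold (log2 1.09 ± 0.11), Igf1r by log2 0.74 ± 0.08, Insr and Pik3ip1 also rose, and the receptor-binding inhibitor Grb14 fell (log2 -0.49 ± 0.10). The list's median was 0.14 (camera adjusted p = 0.00239; adjusted p = 0.105 with an estimated correlation), against 0.09 without DKO replicate 2 or with normexp and quantile normalization. Of 30 autophagy genes 4 rose and 0 fell (10 and 0 adjusted over the list alone), namely Gabarapl1, Bnip3, the lysosomal protease Ctsl (0.96 ± 0.11) and the cargo receptor Sqstm1 (0.54 ± 0.07), with a median of 0.20 (camera adjusted p = 1.73e-05; adjusted p = 0.204 with an estimated correlation). Gabarapl1, Bnip3, Pdk4, Insr, Irs1 and Igf1r passed in all 7 fits with an array left out and the other rises and falls of this paragraph did not. The highest adjusted p was 0.132 for Pink1 without DKO replicate 2. Of 27 proteasome and muscle atrophy genes 0 passed in limma (8 at an unadjusted p below 0.05), and the ubiquitin ligases Trim63 and Fbxo40 gave log2 differences of 0.51 ± 0.15 and 0.38 ± 0.11 (adjusted p = 0.10 and 0.0987 by limma).

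Genes of the fetal and stress program of the heart were higher in part. Myh7, Ccn2, the calcineurin regulator Rcan1 (1.05 ± 0.12), Gdf15 and the cardiac ankyrin repeat gene Ankrd1 (0.87 ± 0.18) rose among 24 members and 0 fell (8 rose and 2 fell adjusted over the list alone). The list's median was 0.16 (camera adjusted p = 0.00631; adjusted p = 0.349 with an estimated correlation), against 0.25 without DKO replicate 2 and 0.27 with the mean of a gene's probes. In the list of extracellular matrix and fibrosis genes, 3 of 39 rose and 0 fell (3 and 0 adjusted over the list alone), namely Ccn2, the matricellular gene Thbs4 (0.69 ± 0.11) and the collagen crosslinking enzyme Lox (0.55 ± 0.09). Of the 39, 33 were higher (median 0.15; camera adjusted p = 5.57e-05; adjusted p = 0.193 with an estimated correlation), and fibroblast markers, which were not called, had a similar median of 0.14, 16 of 22 being higher. Markers of endothelial and mural cells were higher too, with medians of 0.16 and 0.23 (camera adjusted p = 0.00467 and 0.0334; adjusted p = 0.372 for both with an estimated correlation). Among them the smooth muscle myosin Myh11 rose (0.63 ± 0.14) of 16 mural genes (7 rose and 2 fell adjusted over the list alone), and 0 of 25 endothelial genes passed (5 at an unadjusted p below 0.05). Of 34 genes of translation and ribosome biogenesis, 32 were higher and 4 rose (15 adjusted over the list alone). These were Myc (1.33 ± 0.20), the ribosome assembly factor Rrp12 (0.62 ± 0.08), the nucleolar gene Gnl3 (0.58 ± 0.10) and Eif6 (0.31 ± 0.07). Their median was 0.22 (camera adjusted p = 1.88e-08; adjusted p = 0.105 with an estimated correlation). Antioxidant genes of the NRF2 response had 4 of 26 members higher and 0 lower (6 and 0 adjusted over the list alone). These were the plasma glutathione peroxidase Gpx3 (1.13 ± 0.11), Srxn1 (0.50 ± 0.08), Nqo1 (0.80 ± 0.13) and Gstm3 (0.48 ± 0.09), with a list median of 0.17 (camera adjusted p = 0.000226; adjusted p = 0.105 with an estimated correlation). Ccn2, Myh7, Rcan1 and Gpx3 passed in all 7 fits with an array left out, and the highest adjusted p among the others was 0.142 for Myh11 without DKO replicate 1. The endothelial call was lost under quantile normalization and with the authors' values (highest adjusted p = 0.0967), and the mural call under these and 4 further settings (highest 0.0978).

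Ion channel and calcium handling genes were lower in DKO hearts. Of 34 members, 6 fell and 0 rose (10 fell and 2 rose adjusted over the list alone), with a median log2 difference of -0.29 (camera adjusted p = 0.00421; adjusted p = 0.163 with an estimated correlation). Kcnj3 and Kcnj5, subunits of the channel that acetylcholine opens in atrial and pacemaker cells, fell by log2 0.89 and 0.62. The pacemaker channel Hcn4, the calsequestrin Casq2, the potassium channel Kcnq1 and the calcium channel subunit Cacna2d1 fell by 0.54, 0.50, 0.60 and 0.37. Markers of atrial and conduction tissue, of which Kcnj3 and Hcn4 are also members, had a median of -0.09 (camera adjusted p = 0.478). Fatty acid oxidation genes changed in both directions, 3 of 41 rising and 3 falling (6 and 8 adjusted over the list alone). Angptl4, Pdk4 (1.37 ± 0.14) and the acetyl-CoA carboxylase Acaca (0.47 ± 0.10) rose, of which none is an enzyme of beta-oxidation. Ech1 (-0.82 ± 0.09), the thiolase Acaa2 (-0.53 ± 0.09) and the carnitine carrier Slc25a20 (-0.50 ± 0.09) fell. Ech1 lies 40 tested genes from Akt2 on chromosome 7 in the GRCm38.p6 gene order. The list's median was -0.18 (camera adjusted p = 0.0182; adjusted p = 0.511 with an estimated correlation). None of the 6 channel genes passed in all 7 fits with an array left out (highest adjusted p 0.132 for Cacna2d1 without DKO replicate 2). Of the fatty acid genes Angptl4, Pdk4 and Ech1 did, whereas Acaa2 passed in 2, Slc25a20 in 1 and Acaca in 0 (adjusted p up to 0.135 for Acaca without DKO replicate 1). The fatty acid list lost its call with array weights and without control replicate 2 (highest adjusted p = 0.104).

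Other metabolic and contractile genes moved little as groups. Among 34 genes of glycolysis the glucose transporter Slc2a1 (0.73 ± 0.11) and Ugp2 (0.59 ± 0.12) rose (2 and 0 adjusted over the list alone; median 0.01). Of 52 genes of mitochondrial respiration 0 passed (11 at an unadjusted p below 0.05), with Cycs at -0.35 ± 0.08 (adjusted p = 0.0577 by limma; median -0.04). Myom2 rose (0.58 ± 0.08) among 29 sarcomere genes, and Fdft1 rose (0.55 ± 0.08) among 34 genes of sterol and lipid synthesis. In the heat shock list Hspb1 rose (0.52 ± 0.08) and Hspb3, Fkbp4 and Hspb2 fell (-1.06 ± 0.13, -0.35 ± 0.07 and -0.34 ± 0.07). Of apoptosis and p53 genes Bcl2 rose (0.99 ± 0.09) and Gadd45g fell (-0.52 ± 0.11). Of angiogenesis and hypoxia genes Bnip3 and Slc2a1 rose while Angpt1 and Fgf1 fell (-1.09 ± 0.15 and -0.53 ± 0.08). None of these lists passed the camera test, the adjusted p ranging from 0.0772 for angiogenesis to 0.591 for heat shock. Among cytokine genes Ccl12 fell (-0.90 ± 0.11) and Socs3 rose (0.39 ± 0.08), with a camera adjusted p of 0.0579 for the list. Of interferon response genes, 0 of 36 passed (2 at an unadjusted p below 0.05; camera adjusted p = 0.240). An array of each group was low in that list, DKO replicate 1 at -0.19 against 0.12 and 0.22, and control replicate 1 at -0.19 against 0.05 to 0.08. Without that control the median was 0.02 with 20 of 36 higher. Without that DKO array the list's median went from 0.08 to 0.22, with 30 of 36 higher (camera adjusted p = 0.000449 at the preset correlation; adjusted p = 0.791 with an estimated correlation and all arrays), and without DKO replicate 3 it was -0.01. Clock genes included falls of Per3 (-0.86 ± 0.10) and Hlf (-0.72 ± 0.12) and a rise of Arntl (0.49 ± 0.10), with a camera adjusted p of 0.395. Bcl2, Bnip3 and Per3 kept their calls in all 7 fits with an array left out, and the highest adjusted p among the others was 0.141 for Arntl without DKO replicate 1.

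Immediate early genes, which respond within minutes to stimulation or handling, were higher in DKO, with 24 of 25 members above control and 3 past the threshold (3 adjusted over the list alone). These were Ppp1r15a, Myc and Socs3, and the list's median was 0.37 (camera adjusted p = 4.83e-06; adjusted p = 0.269 with an estimated correlation). The values per array were 0.26, 0.29 and 0.57 in DKO and lay between -0.19 and 0.12 in control. Cell cycle genes had a median of -0.62, with 30 of 37 lower and 0 past the threshold (0 adjusted over the list alone, 3 at an unadjusted p below 0.05); Rrm2 and Ccne1 gave -1.26 ± 0.35 and -0.81 ± 0.23 (adjusted p = 0.0861 and 0.0968 by limma). The camera call of that list (adjusted p = 0.00631; adjusted p = 0.652 with an estimated correlation) went with a spread in control from -0.68 to 0.76 that overlapped the DKO range of -1.36 to -0.17. It was lost with slide row as a block and without control replicate 4 or DKO replicate 1 (highest adjusted p = 0.193), where the medians were -0.43, -0.36 and -0.38; over other settings the median ran from -0.96 with array weights to -0.32 with normexp and quantile normalization. Cardiomyocyte markers, with Ttn at -0.32 ± 0.07 and Ryr2 at -0.38 ± 0.10, had a median of -0.05 and 0 of 20 past the threshold (5 at an unadjusted p below 0.05; camera adjusted p = 0.478). Fibroblast markers had a median of 0.14 (camera adjusted p = 0.0518). Macrophage, lymphoid and granulocyte, erythroid, adipocyte, mesothelial, skeletal muscle and Schwann cell markers had medians of 0.06, 0.14, 0.17, 0.12, 0.11, 0.18 and 0.15, none of them called. Without DKO replicate 1 the fibroblast, macrophage and erythroid medians became 0.18, 0.17 and 0.38 and passed at the preset correlation (camera adjusted p = 0.00275, 0.0142 and 0.00275). With an estimated correlation and all arrays the adjusted p was 0.658, 0.839 and 0.658, and without DKO replicate 2 the macrophage and erythroid medians were -0.01 and 0.02. The means of the skeletal muscle and Schwann cell lists had the other sign, at -0.03 and -0.02.

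In all, 13 of 24 pathway and technical lists and 2 of 12 marker lists passed the camera test with its preset correlation, and 0 of them with an estimated correlation (7 and 0 at an unadjusted p below 0.05; directional fry called 12 and 3), where the lowest adjusted p values were 0.105 and 0.372. An exact two-sided permutation test of each list's mean over the 35 splits of the arrays, chosen after the data were seen, ranked the real split first for 12 of the 24 pathway and technical lists. Of these 11 were among the 13 called, with cell cycle and fatty acid oxidation as the exceptions, and the other was the proteasome and muscle atrophy list, which camera did not call. Both called marker lists ranked first as well. The p of 0.0286 is the smallest that test can give and became 0.0571 after adjustment over the 24 lists and 0.171 over the 12 marker lists. With single arrays left out, the median moved by over 1.5 times in 4 of the 15 called lists and in 18 of the 21 others, of which 5 changed sign.

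**Figure D3:**
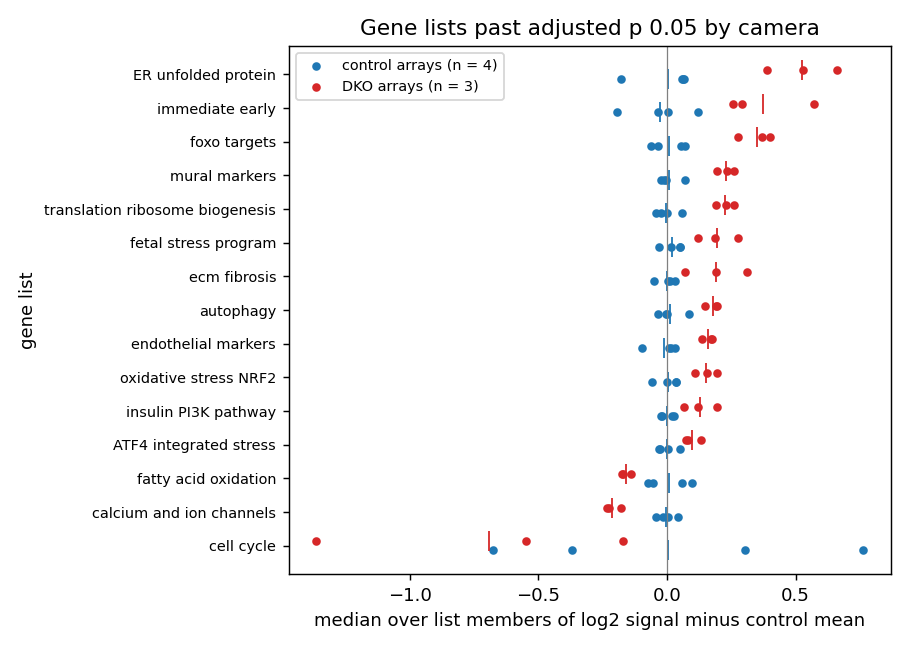
For each gene list past the camera threshold, the median over its members of the log2 signal minus the member's control mean, per array, with control arrays (n = 4) in blue, DKO arrays (n = 3) in red and group means as vertical ticks. The ER list was highest in DKO, at 0.39 to 0.66, and the control and DKO arrays overlap in the cell cycle list.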

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

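The tests of cardiomyocyte share, of control replicate 1 and of handling below were chosen only after the results were seen, whereas the count over splits of the arrays was planned. Among 221 values tested over the 4 control arrays, 12 had 1 array far from the rest, and chance gives about 1 in 20; groups of 3 were not tested. Control replicate 1 was that array in 9 of the 12. Its replicate probes varied by 9.23% against 3.96% to 4.21% in the other controls (gap over range 0.952), and its negative controls averaged -5.85 against -5.06 to -4.94 (0.864). It was low in the ER list (gap over range 0.974), in the interferon response list (0.888) and in the macrophage markers (0.884). It was also low in Dnajb9 (0.831), Myc (0.842) and Ifit2 (0.876) and high in Fbxo40 (0.837). Control replicate 3 was low in Fgf1 (0.856) and high in Txnip (0.855), and control replicate 2 was high in the mitochondrial respiration list (0.851).

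The higher ER and unfolded protein list in DKO hearts was weighed against 3 technical explanations. Control replicate 1 does not account for it, since without that array the list's median difference was 0.48, against 0.55 with it, and the camera call held (adjusted p = 3.62e-09, with adjusted p at most 2.58e-08 over 20 alternatives but 0.169 with an estimated correlation). A lower share of cardiomyocytes would raise the markers of the other cell types alike and by at least as much. However, the 10 lists of types other than cardiomyocytes had a median of 0.15 (SD 0.05) and ran from 0.06 to 0.23. This check covers the ER list only, and not a gain of a single cell type. Inside that range lay the called translation, autophagy, NRF2, fetal program, matrix, insulin and ATF4 lists (medians 0.09 to 0.22). For those lists a change in cell share was not tested. Handling of the tissue stays open, because immediate early genes such as Myc and Ppp1r15a were higher as well. The median of their list was 0.37 (camera adjusted p = 4.83e-06, and adjusted p = 0.269 with an estimated correlation). The handling of each heart is not recorded in the labels. Ppp1r15a is also in the ATF4 list and Myc in the translation list, so neither marks handling alone. Loss of Akt1 and Akt2, the difference the design names, stays open beside handling and was not tested separately.

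For the counts of genes, the real grouping of the arrays ranked first of the 35 splits. Chance alone gives that rank in 2.86% of cases, the smallest share that 35 splits allow, so chance is not excluded. The other splits mix DKO and control arrays, so a real difference widens their spread and lowers their counts of called genes. They also ignore slide row, which was shared unevenly between the groups. Of the 35 ways to split the 7 arrays into 4 and 3, 1 gave as many as 1114 calls, the real one, and the highest of the others gave 39. At 2-fold, 1 of 35 gave as many as 211, again the real one, and the highest other split gave 29. For the counts of gene lists, other splits reached the count of the real split. At least 13 pathway and technical lists were called in 6 of the 35 splits (15 in the highest other split). The other splits among these either swapped 1 DKO array for a control or joined 1 control to the DKO arrays. They kept much of the real contrast, so they cannot show whether a count of 13 is unusual. Splits with 1 DKO array in the group of 3 called 1 to 12 such lists. At least 2 marker lists were called in 19 splits (5 in the highest other split). A count of 13 called lists may still arise from correlation among list members, which these splits do not settle. The calls of single genes such as Irs1, Pdk4 or Chac1 rest on the gene test.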

How the results depend on the processing

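Akt2 was lower under all 20 alternatives, with log2 differences from -2.09 to -1.67. Its call was lost only with the replicate block (-2.06, adjusted p = 0.111), a fit that leaves few residual degrees of freedom. Akt1 differences ran from 0.07 to 0.32, never past the threshold. The 1114 calls became 709 with normexp and quantile normalization, 549 with normexp and the 75th percentile, 121 without a filter on dim probes, and 2028 with trended and robust variances. They became 1680 with array weights, 288 with slide row as a block, 1 with the replicate block (4755 genes at an unadjusted p below 0.05) and 160 to 1127 with an array left out. In the order of those settings, genes higher in DKO (571) numbered 345, 272, 54 and 1095, then 134 with slide row and 0 with the replicate block in limma, and 71 to 384 with an array left out. Genes lower (543) numbered 277 with normexp and the 75th percentile, 67 without a filter, 933 with trended variances, 831 with array weights, 154 with slide row, 1 with the replicate block and 89 to 743 with an array left out. Genes at 2-fold (211) numbered 64 and 69 with the normexp settings, 88 without a filter, 140 with probes above background on all 7 arrays, 116 with slide row, 1 with the replicate block and 91 to 374 with an array left out. The 13 called lists became 0 with an estimated correlation (7 at an unadjusted p below 0.05), 0 with the exact permutation of list means, 22 with fry in either direction and 12 to 15 with an array left out. The 2 called marker lists became 0 with quantile normalization, the authors' values, an estimated correlation or the exact permutation, 1 with normexp and quantile normalization or with probes above background on all 7 arrays. They became 4 with normexp and the 75th percentile, no filter or the replicate block, 10 with fry in either direction, and 1 to 5 with an array left out. Settings without a filter tested 45553 genes, and those that leave out an array had fewer samples. For the others the cause was not tested. Slide row was shared unevenly between the groups. Control replicates 1, 3 and 4 and DKO replicate 3 lay in row 1, and control replicate 2 and DKO replicates 1 and 2 in row 2. Differences between the groups thus cannot be fully told apart from those between slide rows. Without control replicate 2, 34.1% of calls were higher in DKO, against 51.3% with all arrays.

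Replicate numbers did not pair the arrays: same-numbered arrays correlated at 0.129, 0.007 and 0.033 in their deviations from the group means, and only DKO replicate 1 correlated best with its own number. The alternatives reused the same arrays, which left little room for a reversal. None of 106 called genes (those the text names and the called members of every list) or of the 15 called lists reversed under any alternative. These genes kept their calls in 993 of 1147 cases over 11 settings of values or variance, in 398 of 742 with an array left out, in 54 of 106 with slide row as a block and in 0 of 106 with the replicate block. Of the called lists, 10 of 15 kept their call under all 20 alternatives of values, fit and arrays, among them the ER, FoxO target, autophagy and ion channel lists, but 0 of 15 kept it with an estimated correlation or with the exact permutation. The smallest p of the permutation test, 0.0286 before adjustment, left it little room to call a list. Of genes not called, 33 of 71 passed in at least 1 setting, and 10 of 21 lists. Leaving out the neighbours of Akt1 and Akt2, chosen after seeing the data, gave 1091 calls and a median of -0.16 for fatty acid oxidation. Between 44.3% and 49.1% of probes were not well above background on an array, which limits what can be said of dim genes such as Derl3 and Ctcfl.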

Other observations

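The genes in this paragraph were chosen after their values were seen. Mhrt, a noncoding RNA transcribed antisense to Myh7, was lower in DKO hearts (log2 -1.02 ± 0.18, SE, n = 4 and 3, adjusted p = 0.0322 by limma) where Myh7 rose, and Myh6, the adult alpha myosin heavy chain, differed by -0.03 ± 0.08 (adjusted p = 0.827). No class of genes was tested here. Among secreted factors Fgf16 fell 2.35-fold (log2 -1.23 ± 0.18), the vessel factor Angpt1 2.12-fold, Bmp7 1.98-fold and Egf 1.95-fold (log2 -0.96 ± 0.11), while Gdf15, Fgf6 and Ccn2 rose. The orphan receptor Gpr22 fell 2.32-fold (log2 -1.21 ± 0.14), the alpha-1B adrenoceptor Adra1b 1.98-fold (log2 -0.99 ± 0.12), the muscarinic receptor Chrm2 1.67-fold and Mas1 1.86-fold, with Mas1 above background on 2 of the 3 DKO arrays. Of these genes Egf passed in all 7 fits with an array left out, Gpr22 and Adra1b in 6, Angpt1 in 5, Fgf16 in 4, Mhrt in 3 and Bmp7, Chrm2 and Mas1 in 2.

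The tests around Akt2 and Akt1 in this part were chosen after the results were seen. Called genes were dense around Akt2 on chromosome 7. Among Akt2 and the 50 tested named genes on either side of it in the GRCm38.p6 gene order, 11 were called, Akt2 included, 5 of them higher and 6 lower. The 10 neighbours included Blvrb (0.98), Gmfg (0.96), Coq8b (0.41) and Fbxo27, which rose, and Lgals4 (-2.52), Zfp974 (-1.37), Ech1 (-0.82), Map3k10 (-0.47 on its brightest probe) and Mrps12, which fell; Coq8b passed in 0, Map3k10 in 2 and Zfp974 in 4 of the 7 fits with an array left out. Windows of this size elsewhere held a median of 5 calls and at most 13; 1.71% of them held as many as the Akt2 window (3.23% as many as its 10 neighbours), but this count was made after the gathering had been seen, and the windows overlap, so a chance gathering stays open. The densest window of all, with 15 calls, was reached at Fbxo27, 30 tested genes from Akt2.

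Strain variants carried along with a floxed allele may account for these neighbours, in which case Lgals4 and Ech1 could differ through linkage and not through Akt loss. The window around Akt1 on chromosome 12, which the same explanation would enrich, held 7 calls, including Zfp386 (-1.19) and Ptprn2 (0.77), and 27.7% of windows elsewhere held as many. Akt1 lies near the end of its chromosome and its window was not centred on it; the explanation stays open for Akt2 and finds no backing at Akt1. Whether a variant lies under single probes was also left open: of 4 other kept probes of the called neighbours, 1 showed the same sign and at least 50% of the difference, the second Lgals4 probe at -1.94, and both other Map3k10 probes had the opposite sign (0.21 and 0.12). An effect of Akt2 loss on its neighbours was not tested, and it cannot be told apart from strain variants with these arrays.

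Akt1 signal was not lower in DKO hearts although Akt1 was targeted. A mislabelled array is argued against by Akt2, whose lowest control value lay 1.94 above its highest DKO value on the log2 scale, where the pooled SD was 0.06. Of 2 kept Akt1 probes 0 fell past the threshold, and both were higher in DKO (limma, unadjusted p = 0.0492 and 0.0232). Probes outside the deleted exons, or Akt1 RNA mostly from other cells, could leave the signal as it is, and no value here decides between these and a recombination that spared Akt1.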
